A study of Drosophila melanogaster with 6 samples.

How the data were processed

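The data were mRNA-seq libraries of Drosophila melanogaster S2 cells, 3 from wild-type cells and 3 from Tailor (CG1091) knockout cells made with CRISPR/Cas9, grouped by their titles and genotype labels. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected, and libraries were made with a directional NEBNext kit. Each library had a deposited gene table of FPKM values with the bounds of a confidence interval and a status, in the format of Cufflinks per the file headers. The authors' deposited comparison table held group means of normalised counts (a signal per gene), their fold ratio, its log2 and raw and adjusted p-values, with DESeq column names per the file headers. The submitters' processing notes name BWA 0.6.1, TopHat 1.4.1, Cufflinks 1.3.0, HTSeq 0.6.1p1 and DESeq 1.10.1, without roles or parameters. The genome build and annotation are not given in the sources used here, so coordinates are those of the files, 1-based. The log2 values of the authors' deposited table are wild type over knockout, and their sign was turned so that every change here is knockout over wild type.

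The tables hold no counts, so no count model was the main test. Cufflinks intervals give an effective fragment number per gene, the square of 2 times the FPKM over the distance to the upper bound. In genes with 1 transcript, 93.2% to 93.6% of values under 30 were within 0.02 of a whole number. For genes with several transcripts the number is only an effective one. The recovered totals were 18411809 to 22957816 per library, and the FPKM sums were 665278 to 677330 in wild type and 621110 to 656344 in the knockout. In no pair of libraries did more than 0.014% of tested genes share the same FPKM.

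Genes with a mean of at least 1 FPKM over the 6 libraries (7259 of 14210) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 22 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members (20) were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. With fry, which compares no list with other genes, 15 lists passed in 1 direction and 20 when either direction counted. Chromosome arms were compared with Fisher's exact test. Intronic microRNA hosts came from the Ensembl annotation of BDGP6 matched by gene identifier, with mirtrons defined by both ends within 5 nt of the splice sites. Exon lengths from that annotation covered 6911 tested genes (95.2%). Tests of microRNA seed sites in 3' UTRs, which had been planned, need sequence that was not used here and were not run.

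Named genes were Tailor, then the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, then up to 4 called members of each list by smallest p (or 2 members by level where none was called), and up to 3 called genes within 50 kb of CG1091. Of the 106 genes this gave, 30 overlap another listed gene, 22 of them one that was tested.

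The test was tried on simulated data for 7259 genes in 3 against 3 libraries, with 200 genes changed. It recovered 41 of 50 genes at a fold change 25% above 1, 47 of 50 at 1.5-fold and 50 of 50 at both 2-fold and 4-fold, and called 11 of 7059 unchanged genes. The median residual SD was 0.0736 in the simulation and 0.0718 in the data. The simulation changed far fewer genes than the data called (62.1% of those tested), and it held no trend with length. Its rate of false calls therefore does not carry over to the data.

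Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of 5 FPKM, median scaling, quantile normalization, eBayes without trend and robust settings, the replicate number as a block, leaving out each replicate, a 2-fold threshold, camera with an estimated correlation and the authors' deposited table. For lists, the deposited table was tested with cameraPR on its log2 changes alone, without the spread between libraries. That alternative therefore changed the statistic as well as the data. Chosen after seeing the data were the restriction to genes with status OK, limma-voom on recovered fragments and the lists without CG1091. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.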

Results

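Polyadenylated RNA was sequenced from Drosophila melanogaster S2 cells, a cultured line of embryonic origin that resembles hemocytes, the blood cells of the fly. Of the 6 libraries, 3 came from wild-type cells and 3 from cells made deficient in Tailor (CG1091) with CRISPR/Cas9. Tailor is a terminal uridylyltransferase, an enzyme that adds uridines to RNA 3' ends, and the series title names hairpin RNAs as its substrates. The comparison of the groups asks which polyadenylated transcripts differ when Tailor is disrupted. The labels call the knockout samples biological replicates but do not say that the wild-type libraries came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical. Each library listed 14210 genes in FPKM (fragments scaled by transcript length and library size). Fragment numbers recovered from the deposited confidence intervals summed to 20896005, 21346155 and 22957816 in the wild-type libraries and to 19053188, 22536308 and 18411809 in the knockout libraries. Across the 7259 genes tested, which are not independent replicates, log2 levels correlated at 0.9962 to 0.9972 between wild-type libraries, 0.9965 to 0.997 between knockout libraries and 0.9662 to 0.9701 between the groups.

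Tailor mRNA was present in all 3 knockout libraries, at a lower level than in wild type. The gene CG1091 (FBgn0037470, chromosome 3R, 2908945 to 2911811 in the files' own coordinates) stood at 50.7, 51.3 and 47.7 FPKM in wild-type libraries and at 22.3, 26.1 and 26.1 FPKM in knockout libraries. Its mean fell from 49.9 ± 1.95 to 24.8 ± 2.17 FPKM (SD, n = 3 per group), a log2 change of -0.98 (SE 0.063, limma adjusted p = 2.5e-07). The authors' deposited table gave a log2 change of -0.97 for CG1091. These values rest on 2087 to 2132 recovered fragments per wild-type library and 876 to 1148 per knockout library, for a counting error of at most 3.4% in any library. The span of CG1091 overlaps the end of Dpck, whose log2 change was 0.01 (adjusted p = 0.943). A gene-level value does not show which part of the transcript was edited, so it gives the amount of mRNA and not its coding content.

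Heat shock genes rose most in the knockout cells, and genes of folate metabolism, amino acid transport and cytochrome P450 families were among those that fell most. Hsp27, a small heat shock protein, rose 16.0-fold from 57.9 ± 4.18 to 926.9 ± 24.2 FPKM (SD, n = 3 per group), and Nmdmc, a mitochondrial folate enzyme, fell 12.2-fold from 312.8 ± 5.44 to 25.7 ± 1.32 FPKM. In all, 4509 of 7259 tested genes (62.1%) passed an adjusted p of 0.05 in limma, 2182 of them higher and 2327 lower in the knockout. Most of these changes were small, with 3596 called genes (79.8%) under 1.5-fold. At least 2-fold changes were found in 291 genes, 178 higher and 113 lower. The groups did not overlap in 4886 tested genes (67.3%), where chance gives 10% for 3 libraries against 3. The authors' deposited table, a DESeq result for 11643 genes, listed 4193 genes at an adjusted p under 0.05, 2060 higher and 2133 lower in the knockout. At least 2-fold changes were more numerous there, at 648 genes, 428 higher and 220 lower. Among the 7160 genes in both, 3844 were called in both and all 3844 in the same direction. Log2 changes are on the log2(FPKM + 1) scale, which understates those of low genes. With 1 knockout group, no test here separates the edited gene from the history of the edited cells.

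**Figure D1:**
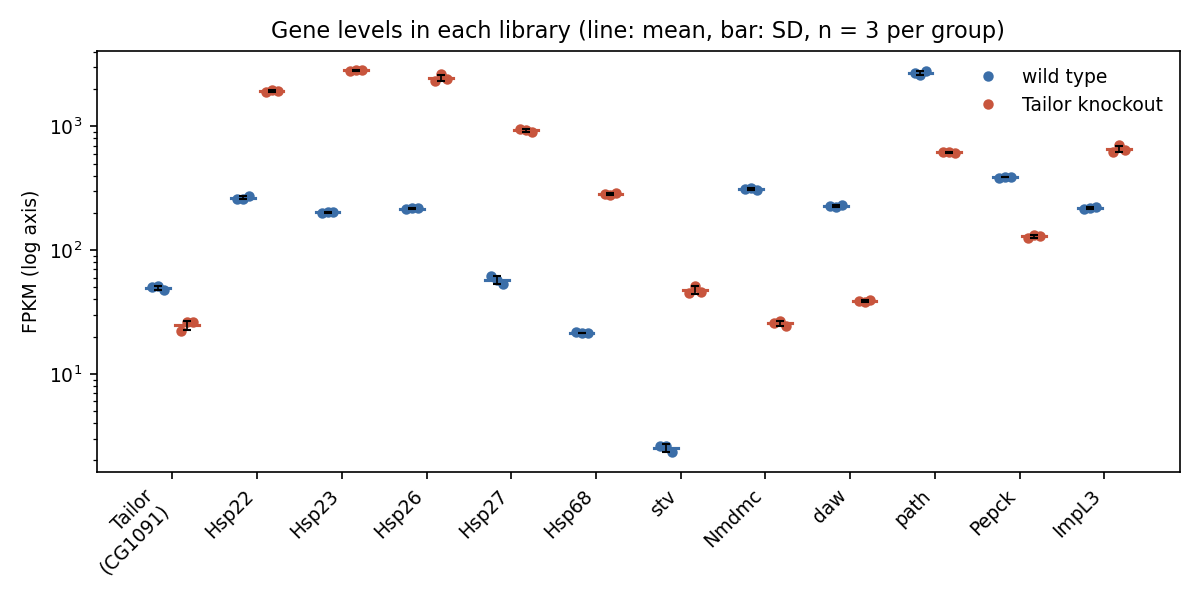
FPKM (log axis) of Tailor and 11 other named genes in each library, with wild type in blue and Tailor knockout in red; lines are means and bars SD, n = 3 per group. Tailor lies between 22.3 and 26.1 FPKM in the knockout libraries, and Hsp27 between 901.4 and 949.5 against 53.8 to 62.1 in wild type.

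The 12 largest rises were in stress genes. Small heat shock genes of 1 cluster on chromosome 3L rose to high levels: Hsp23 from 201.7 ± 2.86 to 2837 ± 26.6 FPKM (log2 3.81), Hsp26 from 217.0 ± 2.12 to 2464 ± 153 FPKM (log2 3.50) and Hsp22 from 264.5 ± 7.21 to 1934 ± 34.3 FPKM (log2 2.87). Hsp67Bc, of the same cluster, rose from 0.753 ± 0.168 to 14.4 ± 1.23 FPKM. Starvin (stv), a BAG-domain co-chaperone, rose from 2.52 ± 0.174 to 47.6 ± 3.46 FPKM (log2 3.79), and the chaperone gene Hsp68 from 21.5 ± 0.128 to 285.0 ± 5.34 FPKM (log2 3.67). The heat-inducible noncoding alphagamma-element:CR32865 rose from 13.1 ± 0.215 to 192.9 ± 1.80 FPKM. Hsp70Ba, Hsp70Bb, Hsp70Bbb and Hsp70Bc rose by log2 3.41, 3.49, 2.72 and 3.44, but these near-identical copies share reads, and how the authors' pipeline divided them is not given in the sources used here. The largest adjusted p among the 12 was 5.76e-10.

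Among the 12 largest falls were metabolic and signalling genes. The cytochrome P450 genes Cyp28d1 and Cyp6a14 fell from 83.1 ± 1.17 to 9.30 ± 0.457 FPKM and from 20.6 ± 0.433 to 1.77 ± 0.501 FPKM. The gene daw, encoding an activin-type ligand, fell from 227.8 ± 4.96 to 38.8 ± 0.491 FPKM (log2 -2.52). Path, an amino acid transporter gene, fell from 2709 ± 99.3 to 617.7 ± 3.94 FPKM (log2 -2.13), and CG5535, another transporter gene of that kind, from 239.4 ± 5.76 to 67.3 ± 1.70 FPKM. The serine synthesis enzyme gene aay fell by 2.04 on the log2 scale, and the adenylyl cyclase gene Ac78C by 2.19. Fie, CG31918, CG9505 and CG3984 completed the group with log2 changes of -3.53, -2.42, -2.38 and -1.82. The largest adjusted p among the 12 was 1.08e-08. The span of Nmdmc contains Rel, an immune transcription factor gene that rose (log2 0.45, adjusted p = 7.12e-06). Whether reads were assigned by strand is not given in the sources used here, so the values of this pair are uncertain. The same holds for aay, which lies within the span of CG3967. It also holds for Hen1 and mdy, named below, whose spans contain CG8878 and Cas. Likewise elav and Syx1A, named below, lie within the spans of arg and 4EHP.

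All 15 tested heat shock genes rose, and glycolytic genes rose with them. The heat shock list had a median log2 change of 3.40 and 14 members up at least 2-fold, with 15 members past the threshold adjusted over the list alone (camera adjusted p = 2.42e-14). It was the 1 list of 20 that also passed with an estimated correlation, at an adjusted p = 0.0238. Of 18 tested genes of glycolysis and sugar use, 15 rose, 1 fell and 2 did not pass, with 16 past the threshold adjusted over the list alone (median log2 0.99, camera adjusted p = 1.29e-07, and adjusted p = 0.275 with an estimated correlation). Pgi, which follows hexokinase in glycolysis, rose from 47.1 ± 1.13 to 154.8 ± 6.39 FPKM, the trehalose-splitting Treh from 15.6 ± 0.476 to 51.6 ± 0.298 FPKM and the oxygen-sensing prolyl hydroxylase gene Hph from 73.1 ± 1.74 to 187.2 ± 3.68 FPKM. The member that fell, Pepck, encodes a gluconeogenic enzyme and went from 390.2 ± 3.16 to 129.6 ± 3.55 FPKM (log2 -1.58).

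Genes of DNA damage and apoptosis were mostly higher in the knockout: 13 of 20 rose, 1 (egr) fell and 6 did not pass, with 14 past the threshold adjusted over the list alone (median log2 0.25, camera adjusted p = 0.00812, and adjusted p = 0.275 with an estimated correlation). The proapoptotic gene rpr rose from 6.28 ± 0.169 to 19.6 ± 0.640 FPKM, the initiator caspase gene Nc from 31.3 ± 0.749 to 47.5 ± 0.285 FPKM and the end-joining gene Ku80 from 10.2 ± 0.862 to 18.7 ± 0.548 FPKM. In the JAK-STAT list 7 of 11 genes rose, 1 fell and 3 did not pass, with 8 past the threshold adjusted over the list alone (median log2 0.21, camera adjusted p = 0.0253, and adjusted p = 0.275 with an estimated correlation). Socs36E, a feedback inhibitor of that pathway, rose from 75.4 ± 3.85 to 206.5 ± 2.70 FPKM and the stress-induced TotM from 2.95 ± 0.310 to 9.31 ± 0.800 FPKM, while Stat92E, the pathway's transcription factor, fell by 0.28 on the log2 scale. With quantile normalization the JAK-STAT list stood at an adjusted p = 0.0504 (0.00541 to 0.275 over its alternatives). With the log2 changes of the authors' deposited table the DNA damage list stood at an adjusted p = 0.0662 (0.00236 to 0.275 over its alternatives).

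Subunits of oxidative phosphorylation were lower in the knockout: 58 of 67 tested genes fell, 0 rose and 9 did not pass, with 58 past the threshold adjusted over the list alone (median log2 -0.36, camera adjusted p = 1.46e-10, and adjusted p = 0.475 with an estimated correlation). The cytochrome c oxidase subunit gene cype fell from 201.2 ± 4.59 to 135.4 ± 9.17 FPKM, CG18624 from 139.0 ± 1.38 to 95.5 ± 5.42 FPKM and CG7630 from 286.3 ± 6.91 to 188.8 ± 14.8 FPKM. Of 87 genes for cytosolic ribosomal proteins, 68 fell, 2 rose and 17 did not pass, with 70 past the threshold adjusted over the list alone (median log2 -0.24, camera adjusted p = 4.08e-08, and adjusted p = 0.624 with an estimated correlation). RpS13 fell from 3744 ± 113 to 2355 ± 172 FPKM and RpLP0 from 1647 ± 22.3 to 1130 ± 66.7 FPKM. RpS5b, a second copy of a ribosomal gene, fell by 1.16 on the log2 scale. The 2 that rose were RpS19b (log2 1.21) and RpL5 (log2 0.28), the latter named after its value was seen. With quantile normalization the ribosomal list had a median log2 change of -0.04 and an adjusted p = 0.254 (7.77e-12 to 0.624 over its alternatives). Short transcripts were lower in general: of 10 groups by exon length, the shortest (median 677 nt) had a median log2 change of -0.19 and the longest (median 7453 nt) 0.11.

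**Figure D2:**
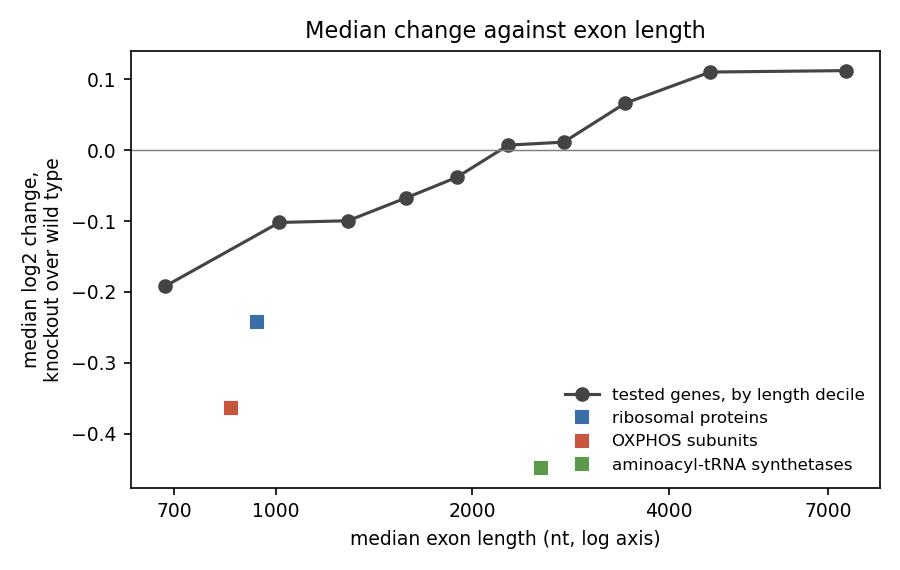
Median log2 change, knockout over wild type, against median exon length (nt, log axis) for 10 length groups of the 6911 tested genes with an annotated length (grey circles), with squares for members with a length of 3 gene groups. The medians of the length groups run from -0.19 to 0.11, and the OXPHOS subunits lie at -0.36.

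The list of RNA 3' end enzymes and exosome genes, which includes Tailor, was lower in the knockout. Of 18 tested genes, 13 fell, 1 rose and 4 did not pass, with 14 past the threshold adjusted over the list alone (median log2 -0.27, camera adjusted p = 0.00639, and adjusted p = 0.275 with an estimated correlation). Without CG1091, the edited gene, 12 of 17 fell, 1 rose and 4 did not pass, with 13 past the threshold adjusted over the list alone (median log2 -0.25, camera adjusted p = 0.0127, and adjusted p = 0.275 with an estimated correlation; 0.00247 to 0.275 over the list's alternatives). The exosome gene Csl4 fell from 20.1 ± 0.951 to 12.2 ± 1.34 FPKM, and the exosome genes Rrp6 and Rrp4 had log2 changes of -0.56 and -0.49. The 1 member that rose, hrg, was named after its value was seen (log2 0.14). This list was not matched on exon length, and short transcripts were lower in general, so its fall may partly go with length. Of 29 genes of the cell cycle and DNA replication, 16 fell, 5 rose and 8 did not pass, with 21 past the threshold adjusted over the list alone (median log2 -0.21, camera adjusted p = 0.0475, and adjusted p = 0.275 with an estimated correlation). The phosphatase gene stg, which drives entry into mitosis, had a log2 change of -0.62, and the origin recognition gene Orc2 fell from 18.0 ± 0.327 to 11.1 ± 0.0951 FPKM. The 5 that rose, named after their values were seen, were CycA, CycB, CycD, CycE and BubR1. The cell cycle call in camera was lost with a filter at a mean of 5 FPKM (adjusted p = 0.0589) and with quantile normalization (adjusted p = 0.0519). It was also lost without wild-type replicate 2 (adjusted p = 0.0526) and without knockout replicate 2 (adjusted p = 0.0722). With the authors' deposited table, tested with cameraPR on log2 changes alone, the adjusted p was 0.164. The range was 0.00541 to 0.275 over the alternatives of this list.

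**Figure D3:**
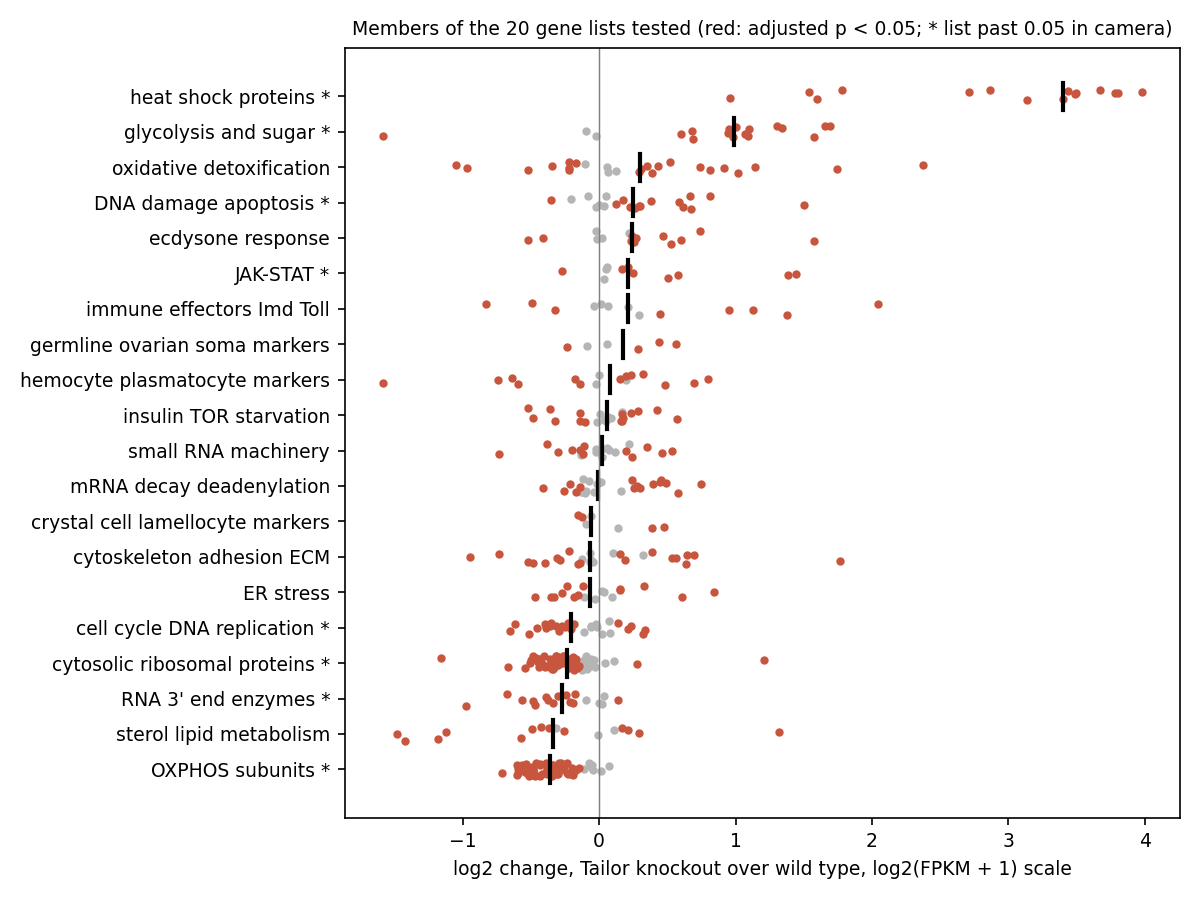
Log2 change, knockout over wild type, of each tested member (points) of the 20 gene lists tested, with list medians as black lines; red points passed an adjusted p of 0.05 and grey points did not. The 15 heat shock genes all lie above 0 around a median of 3.40, and 58 of the 67 OXPHOS points are red and below 0.

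The small RNA machinery did not move as a list, and the 12 of its 21 genes that were called are no larger a share than the 62.1% of all tested genes. Of 21 genes, 5 rose, 7 fell and 9 did not pass, with 10 past the threshold adjusted over the list alone (camera adjusted p = 0.922). Dcr-2, which makes small interfering RNAs, rose from 34.7 ± 0.491 to 50.8 ± 2.98 FPKM, while Hen1, which methylates their 3' ends, fell from 11.6 ± 0.317 to 6.66 ± 1.16 FPKM. The span of Hen1 contains CG8878 (mean 36.8 FPKM over the libraries, log2 0.04), so the value of Hen1 is uncertain. The helicase gene armi fell by 0.38 on the log2 scale, and CG16940, the exonuclease Dis3l2 that degrades uridylated RNA, by 0.30. Of 26 genes of mRNA decay and deadenylation, 10 rose, 5 fell and 11 did not pass, with 15 past the threshold adjusted over the list alone (camera adjusted p = 0.44). The median of that list was -0.01 and its mean 0.09. The decapping cofactor genes tral and Edc3 rose from 55.9 ± 3.28 to 94.7 ± 3.35 FPKM and from 16.8 ± 0.896 to 25.6 ± 0.908 FPKM.

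In the list of immune effectors 5 of 13 genes rose, 3 fell and 5 did not pass, with 8 past the threshold adjusted over the list alone (camera adjusted p = 0.372). The antimicrobial peptide genes Drs and CecA1 rose from 1.59 ± 0.380 to 9.68 ± 1.46 FPKM and from 14.5 ± 1.06 to 32.9 ± 3.96 FPKM, and AttB rose by log2 1.38. Of 25 genes of detoxification and oxidative stress, 13 rose, 8 fell and 4 did not pass, with 21 past the threshold adjusted over the list alone (camera adjusted p = 0.163). The glutathione transferase genes GstD5 and GstE9 rose from 30.9 ± 1.31 to 164.4 ± 14.6 FPKM and from 47.4 ± 3.55 to 161.0 ± 10.4 FPKM. With the log2 changes of the authors' deposited table both lists passed, at an adjusted p of 0.00662 for the immune list (up to 0.712 over its alternatives) and 0.0387 for detoxification (up to 0.68). That test left out the spread between libraries, so its statistic differs from that of the main test.

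Of 16 genes of sterol and lipid metabolism, 9 fell, 4 rose and 3 did not pass, with 13 past the threshold adjusted over the list alone (camera adjusted p = 0.0559). The triglyceride synthesis gene mdy fell from 14.8 ± 0.511 to 4.65 ± 0.157 FPKM, the lipase gene Lip4 from 21.8 ± 0.987 to 9.05 ± 0.699 FPKM and the sterol-binding Npc2a from 82.6 ± 9.27 to 37.2 ± 0.514 FPKM. The member with the smallest p, GNBP2, fell from 171.9 ± 3.16 to 63.5 ± 3.88 FPKM. GNBP2 belongs to a family known for immune recognition, and the list was not tested without it. Of 15 ecdysone response genes, 9 rose, 2 fell and 4 did not pass, with 12 past the threshold adjusted over the list alone (camera adjusted p = 0.0559). ImpL3, which encodes lactate dehydrogenase and belongs to the glycolysis list as well, rose from 219.0 ± 4.45 to 656.5 ± 40.7 FPKM, and the nuclear receptor gene Eip75B from 30.9 ± 3.72 to 47.1 ± 1.79 FPKM. Both lists passed only narrowly with a pseudocount of 5 (camera adjusted p = 0.05 after rounding for each). Both also passed without wild-type replicate 3 (adjusted p = 0.0425 for the lipid list and 0.0355 for the ecdysone list). The lipid list also passed without knockout replicate 1 (adjusted p = 0.0368), without knockout replicate 3 (0.0466), with no filter and with the authors' deposited table. Adjusted p ranged from 0.00541 to 0.275 over the alternatives of the lipid list and from 0.0355 to 0.624 over those of the ecdysone list.

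Of 18 genes of endoplasmic reticulum stress, 5 rose, 8 fell and 5 did not pass, with 14 past the threshold adjusted over the list alone (camera adjusted p = 0.872). The oxidase gene Ero1L rose from 65.0 ± 2.81 to 117.2 ± 1.56 FPKM and the chaperone gene Gp93 from 282.7 ± 6.58 to 430.5 ± 6.09 FPKM. In the insulin, TOR and starvation list 8 of 22 genes rose, 7 fell and 7 did not pass, with 15 past the threshold adjusted over the list alone (camera adjusted p = 0.645). Sesn, a stress-induced inhibitor of TOR, rose from 20.5 ± 0.691 to 31.1 ± 1.07 FPKM, and the secreted insulin antagonist gene ImpL2 fell from 2508 ± 106 to 1749 ± 78.5 FPKM. Of 26 genes of cytoskeleton, adhesion and matrix, 9 rose, 10 fell and 7 did not pass, with 20 past the threshold adjusted over the list alone (camera adjusted p = 0.922). The transferrin gene Tsf1 rose from 1.98 ± 0.281 to 9.12 ± 0.374 FPKM, and trol, which encodes perlecan, fell from 72.9 ± 3.75 to 37.5 ± 2.91 FPKM. This list had a median of -0.06 and a mean of 0.06.

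Markers of cell types moved in both directions. Of 16 plasmatocyte genes, 7 rose, 6 fell and 3 did not pass, with 13 past the threshold adjusted over the list alone (camera adjusted p = 0.922). The matrix gene LanB2 fell from 284.0 ± 6.67 to 187.7 ± 5.01 FPKM, and the matrix genes BM-40-SPARC and LanB1 had log2 changes of -1.59 and -0.64. Ppn, another matrix gene, rose from 56.5 ± 4.06 to 99.0 ± 3.07 FPKM (log2 0.80), but had a status other than OK in 3 libraries and lost its call with limma-voom (log2 2.93, adjusted p = 0.434, the highest of its alternatives, with 6.62e-32 the lowest). This list had a median of 0.08 and a mean of -0.05, and its median was -0.00247 without wild-type replicate 1 and 0.16 without wild-type replicate 2. Of 7 crystal cell and lamellocyte genes, 2 rose, 2 fell and 3 did not pass, with 3 past the threshold adjusted over the list alone (camera adjusted p = 0.872, median -0.06, mean 0.08). The filamin gene cher rose by log2 0.48, and the integrin gene mys fell by 0.16 on the log2 scale. Of 6 germline and ovary genes, 3 rose, 1 fell and 2 did not pass, with 4 past the threshold adjusted over the list alone (camera adjusted p = 0.44). Sxl, the switch gene of sex determination, rose from 41.9 ± 1.66 to 62.4 ± 2.58 FPKM. In the neuron list 3 genes were high enough to test, with Syx1A at log2 0.23, elav at 0.32 and brp at -0.32. In the muscle and fat body list 1 was, Mef2 at log2 -0.39 (adjusted p = 0.000543). Those 2 lists were too small for a list test.

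Genes that host microRNAs in their introns did not shift as a set. Mirtrons are microRNA precursors made by splicing, and Tailor is known to act on them. Of 21 tested mirtron hosts, 7 rose, 8 fell and 6 did not pass, with 15 past the threshold adjusted over the list alone (median log2 -0.0028, camera adjusted p = 0.94). Over all 62 tested microRNA hosts, 21 rose, 23 fell and 18 did not pass, with 44 past the threshold adjusted over the list alone (median log2 0.01, mean -0.01, camera adjusted p = 0.94). The hosts were assigned from an annotation matched by gene identifier. MicroRNA levels and target sites were not analysed here.

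Changed genes lay on every chromosome arm. The share of tested genes called ran from 59.2% on X to 63.9% on 2L, and Fisher's exact test found 0 arms that differed from the rest and 1 at an unadjusted p under 0.05 (X, p = 0.0195, adjusted p = 0.117). X passed in all 9 alternatives run for it, which include leaving out each library in turn, with adjusted p from 0.00421 to 0.0465. Of the called genes on 3L, 53.3% were higher in the knockout (two-sided Fisher's exact test, adjusted p = 0.0101). That call was lost without wild-type replicate 1 (adjusted p = 0.0708), without knockout replicate 1 (0.0716), with a 2-fold threshold and with the authors' deposited table, in a range of 0.0112 to 0.561 over its alternatives. Around CG1091, 5 of the 11 tested genes within 50 kb were called, and all 11 had a median log2 change of 0.07. Alh rose from 8.43 ± 0.245 to 18.1 ± 0.587 FPKM (log2 1.02), CG10098 rose by log2 0.40 and CG1965 fell by 0.19 on the log2 scale.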

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

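The status filter, the voom fit and the lists without CG1091 were chosen after seeing the data. Tailor stayed lower and past the threshold under every setting, with log2 changes from -1.02 to -0.88. Between 4004 and 4542 genes passed under all settings but the authors' deposited table, with 4193 of all its genes and 3928 of the 7160 tested in both, and the 2-fold threshold, which left 291, 61.2% of them higher against 48.4% of 4509. Of those 291 genes, at least 286 were called under every other setting except a filter at 5 FPKM, which removed some (227). Of 1778 settings of named genes, 20 lost the call and 0 reversed. The 4 genes involved were CG10467, brp, osk and Ppn (voom, log2 2.93). Of the 20 lists, 8 passed as reported and without CG1091, 5 with quantile normalization and 1 with an estimated correlation; leaving out a replicate gave 7 to 10. For each of those 8 lists the estimated correlation gave the highest adjusted p of the alternatives, with lowest values from 5.4e-106 (heat shock) to 0.00541 (JAK-STAT and cell cycle). X was the arm that passed, 1 of 6, with the replicate block, with the 2-fold threshold and with the authors' deposited table, and in each fit that left out a replicate (1 to 1). The causes were not tested, though the 2-fold count is lower by construction.

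Lists near 0 changed camera direction without passing in either fit. Small RNA machinery did so with no filter (0.0203), a mean of 5 FPKM (-0.0204), the authors' deposited table (-0.00699) and without wild-type replicate 1 (-0.0158; up to 0.0349 over the fits without a replicate). Plasmatocyte markers did so at 5 FPKM (-0.0107), with voom (0.0492) and in the authors' deposited table (0.0161). Cytoskeleton genes did so with the block (-0.0637), in the authors' deposited table (-0.073) and without wild-type replicates 2 and 3 (-0.0655, -0.0411; fits without a replicate -0.0896 to -0.0411). Without knockout replicate 2, so did mirtron hosts (0.0057; -0.0351 to 0.019 over the fits without a replicate) and all hosts (0.0111; -0.0334 to 0.0213). The cause was not tested.

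The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.049, 0.0029 and -0.032, against -0.055 to 0.077 for unlike numbers. With the replicate block 4393 genes and 8 lists passed. X aside, the block changed no call of a list, of an arm or of Tailor, and the named gene CG10467 lost its call. Planned seed-site tests with longer sites and a matched background were not run, since sequence was not used here. Sequencing depth limits low genes most, and Tailor itself rests on 876 or more fragments per library.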

Other observations

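Chosen after the result was seen were the tests of the heat shock cluster, of scaling, of the ribosomal and OXPHOS parts and of the synthetase set; the tests of adjacent genes were written beforehand, but measuring distance from 0 in either direction and the name-stem rule were settled after the window medians had been seen.

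Several genes for amino acid supply and use fell in the knockout, and some rose. Of 21 aminoacyl-tRNA synthetase genes, 13 fell, 4 rose and 4 did not pass, with 18 past the threshold adjusted over the list alone (median log2 -0.30). The asparaginyl enzyme gene Aats-asn fell from 779.9 ± 38.8 to 233.7 ± 5.65 FPKM (SD, n = 3 per group), Aats-ile, of a status other than OK in all 6 libraries, from 359.7 ± 9.46 to 122.2 ± 2.82 FPKM and Aats-glupro from 141.2 ± 3.01 to 69.4 ± 2.96 FPKM. Of 12 amino acid transporter genes, 8 fell, 2 rose and 2 did not pass (10 past the threshold adjusted over the list alone), with JhI-21 falling from 889.6 ± 22.3 to 299.9 ± 12.1 FPKM and mnd from 189.7 ± 5.29 to 57.2 ± 2.10 FPKM. In serine and folate metabolism 5 of 6 genes fell (5 past the threshold adjusted over the list alone), among them pug (log2 -0.72) beside Nmdmc and aay. The last pair of lists was drawn up after several members had been seen to fall, so their counts are not independent evidence. None of the 3 lists passed camera with an estimated correlation (adjusted p = 0.308 for the synthetases, 0.191 for the transporters and 0.119 for serine and folate genes). The transporter gene CG7888 had a log2 change of 1.11. The genes of this paragraph were named after their values were seen.

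For the synthetases, a coordinated lowering is a hypothesis, which does not cover the fall of transporter, serine and folate genes. A difference in medium between the cultures was not tested. All tested synthetases gave a camera p = 0.0022, and p = 0.308 with an estimated correlation. Aats-asn and Aats-ile had been seen to fall first, before the set was drawn up. Among the 19 others the median was -0.27, with limma's camera at p = 0.0169, and p = 0.389 with an estimated correlation. The 20 synthetases with an annotated length had a median of -0.45, against -0.30 for all 21. Of 10000 random lists matched to them on exon length and level, 0% had a median as low. These draws treat genes as independent, whereas the estimated correlation was 0.365, and no draw left out Aats-asn and Aats-ile. The median is thus lower than those properties give, for this set as drawn up only.

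For the heat shock gene rise, the 31 tested genes of other families within 100 kb of the small heat shock cluster on 3L had a median log2 change of -0.00543 (-2.04 to 1.01), with 9 called higher and 11 lower, which argues against a gain of the whole 100 kb on both sides. The nearest of them on either side, Fdxh (0.37) and CG4080 (1.01), were among those higher, and were named after their values were seen. A narrower gain would not give the rises of Hsp68 (log2 3.67) and Hsp70Bb (3.49) on 3R, nor, if it spanned CR43481 (0.92, named after its value was seen), those of Hsp26 (3.50) and Hsp23 (3.81) on either side of it, though a smaller gain beside another process is not excluded. The called heat shock genes kept a median of at least 3.32 under median scaling and quantile normalization, which argues against scaling. Their mean log2 level spanned 0.04 across the 3 knockout libraries, a value that could not decide between explanations. With 1 knockout group, a stress of the knockout cultures or their harvest, the edited line, and the loss of Tailor cannot be told apart. A stress response that follows from Tailor loss stays among the open, untested explanations.

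The fall of ribosomal protein and OXPHOS genes was set against the trend with length. The OXPHOS genes had a median of -0.36, and 0% of 10000 lists matched on length and level were as low (matched median -0.12). Length and level as matched thus went with part of that fall and not with all of it. The draws treat genes as independent, whereas the estimated correlation within the list was 0.45, so the share of 0% may overstate the case. The highest median of the OXPHOS genes under median scaling and quantile normalization was -0.354, so those scalings did not remove the fall. For ribosomal genes 0.02% of lists were as low, but the match failed (median 2890 FPKM against 206). Their median was -0.0411 under quantile normalization, while the list kept its call under median scaling. Quantile normalization sets the highest values alike in every library. These genes are among the highest, so it could remove a real fall as well. Scaling stays a possible explanation that this test cannot decide. Genes for mitochondrial ribosomal proteins were lower too (median -0.309, 49 of 72 fell, camera p = 2.08e-07, and p = 0.0986 with an estimated correlation). A general fall of nuclear genes for mitochondrial machinery is a hypothesis that goes with these values. They do not single it out, since these genes were not matched on length and level, and enzymes at RNA 3' ends fell as well. The shortest of 10 length groups lay at -0.23, -0.11 and -0.22 in the 3 knockout libraries against the wild-type mean. The longest lay there at 0.16, 0.037 and 0.14. Wild-type libraries, each against the others of their group, lay at 0.011, 0.014 and -0.028 for the shortest group. For the longest they lay at -0.073, 0.074 and 0.0015, a spread that holds the value of knockout replicate 2. No biological explanation of the length trend was tested.

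For the count of changed genes, 3 libraries against 3 make 10 splits, too few for a share under 0.05; 1 split, the real one, reached 4509 genes and the highest other gave 1.

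Over 20 adjacent tested genes, the median log2 change farthest from 0 was 0.42 on 3L, from 224106 to 356050, and 48 of 1000 shuffles along the arms reached as far. Once adjacent genes that share a name stem were thinned to 1, the farthest median was 0.385 and 135 of 1000 shuffles reached as far.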
